A study of Mus musculus with 6 samples.

How the data were processed

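RNA was profiled in 6 libraries of mouse Th9 cells, 3 untreated and 3 treated with sorafenib, grouped by the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V5 RNA-seq kit. The authors deposited whole-number gene counts and a table of FPKM values. Per the submitters' processing notes, fastp, HISAT2, HTSeq, R 3.2.0 and DESeq2 were used with the GRCm39 build. The roles of these tools, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so values of overlapping genes and close paralogs are uncertain. FPKM in the deposited table equalled the count scaled by column total and gene length, which gave the gene lengths used below. The reference annotation at hand is of GRCm38, so no coordinates are given, and its transcripts served only for GC content, which 94.5% of tested genes had.

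Totals were 36981476 to 38126521 counts per library over 21233 genes, and 3 counts, the floor used for a count of 0, corresponded to 0.0787 to 0.0811 CPM. Genes with low counts were removed with filterByExpr, leaving 13255. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F test, robust) in R 4.3.3, with group as the only term, 4 residual degrees of freedom and a common biological coefficient of variation of 10.9%. P-values were Benjamini-Hochberg adjusted over all tested genes, with a threshold of 0.05. Standard errors were derived from the F statistic. Log2 fold changes are sorafenib minus control. CPM are TMM-scaled.

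A total of 50 gene lists, the test, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members, 46 of the 50, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists, and again with an estimated correlation. Of 1174 symbols in the lists, 1086 were in the table and 960 were tested. Symbols were matched as written, so genes held under older symbols, several tRNA synthetase genes among them, counted as not measured. Of the 51 integrated stress response symbols, 42 were in the table. Named genes are the 10 largest rises and 10 largest falls among genes with a mean log2 CPM of at least 3, an adjusted p under 0.05 and groups that do not overlap, 16 genes of Th9, lineage and drug-target interest whatever their result, and up to 4 called members of each list with the smallest adjusted p, or up to 2 with the smallest p where none was called. Some genes that this rule names are not reported here.

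Alternatives were DESeq2 size factors, upper-quartile factors, total counts only, no filter, a stricter filter of CPM of at least 1 in 3 samples, a replicate block, each library left out, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) with and without a filter of 0.5 on mean FPKM and on log2(FPKM + 0.1), stricter thresholds, and for lists fry, rank-based camera and lists without shared genes. Corrections for gene length and GC content were added after seeing the data.

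The gene test was tested on simulated data for this comparison, in 8 draws each with 200 changed genes among about 13080 tested. The real comparison called 2378 of 13255 genes. Fewer changed genes make the adjusted threshold stricter, so the simulated shares may not carry over to the data. With dispersions set gene by gene, 61.1% of genes changed 1.5-fold and 79.7% of genes changed 2-fold were recovered. Of all calls 8.13% were false, above the nominal share, while 4.85% of unchanged genes had an unadjusted p under 0.05. With dispersions on the trend, 66.1% and 83.5% were recovered and 5.32% of calls were false. In the list test a planted list was called in 8 of 8 draws and 0 of 360 unchanged lists were called with either dispersion, but those genes were drawn independently, which real genes are not.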

Results

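RNA-seq gene counts were examined from mouse Th9 cells, a class of CD4 T helper cell known for secreting interleukin 9. The 6 libraries comprised 3 from untreated control cells and 3 from cells treated with sorafenib, a small-molecule inhibitor of RAF and several receptor tyrosine kinases. Total counts per library lay between 36981476 and 38126521 over 21233 genes. A count of 0 in a library allowed up to 0.0787 to 0.0811 CPM (counts scaled to a fixed library total) at a floor of 3 counts, which covers counting error only. The labels number the replicates without saying that they were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Values below are TMM-scaled CPM, given as mean ± SD over 3 libraries per group.

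The comparison asked how the transcriptome of Th9 cells differed with sorafenib. Sorafenib cells had more transcript of Il9, the defining cytokine of the lineage, and of the transcription factors Gata3 and Foxp3. They had less transcript of the cytokines Il10, Il21 and Il24 and of the receptors Il2ra, Tnfrsf9 and Ctla4. Genes of the hypoxia response and of sterol synthesis were lower as groups, while genes of mitosis and of the integrated stress response were higher as groups by camera at its preset correlation. With an estimated correlation none of these 4 lists passed (adjusted p of 0.244, 0.343, 0.246 and 0.343). Of 13255 genes tested, 1128 were higher and 1250 lower with sorafenib at an adjusted p under 0.05 by edgeR's quasi-likelihood test, and 280 and 280 of these differed by at least 2-fold. The groups did not overlap for 2372 of these 2378 genes, and for 36.3% of all tested genes, where chance gives 10%. The count was 4325 without control replicate 2, 1294 without sorafenib replicate 1, 1549 without sorafenib replicate 2 and 1243 without sorafenib replicate 3. Scaling by total counts alone called 1496 higher and 826 lower, and the FPKM values called 1405 higher and 748 lower, so the balance of directions depends on the scaling.

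Il9 transcript was 192 ± 18.8 CPM in control and 266 ± 15.4 CPM in sorafenib cells, 1.39-fold higher (log2 fold change 0.47 ± 0.08 SE, adjusted p = 0.00357). Gata3, which directs the Th2 and Th9 programmes, rose 1.45-fold, from 61.1 ± 8.79 to 88.4 ± 2.92 CPM (adjusted p = 0.00463), and missed the threshold on unfiltered FPKM (adjusted p up to 0.0599 over the alternatives). Foxp3, the lineage factor of regulatory T cells, rose 2.03-fold, from 12.4 ± 1.91 to 25.2 ± 2.4 CPM (adjusted p = 0.000356). Etv5, an ETS factor that promotes Il9 transcription, rose 2.03-fold, from 5.84 ± 0.912 to 11.9 ± 0.929 CPM. Some other factors linked to Il9 did not pass the test: Irf4 had 1408 ± 140.2 CPM in control and 1206 ± 37.2 CPM in sorafenib cells (adjusted p = 0.153), Batf had 191 ± 26.8 CPM in control and 204 ± 6.69 CPM in sorafenib cells (adjusted p = 0.541) and Spi1, which encodes PU.1, had 0.552 ± 0.177 CPM in control and 0.928 ± 0.0835 CPM in sorafenib cells (adjusted p = 0.2). Irf4 was called, as lower, without control replicate 2 (adjusted p = 0.000236) and with the gene length trend removed (adjusted p = 0.0268), and Batf, as higher, without control replicate 2 (adjusted p = 0.00383). Il24 fell 3.43-fold, from 351 ± 7.71 to 102 ± 12.8 CPM, Il10 fell 2.58-fold, from 132 ± 19.1 to 51.03 ± 2.59 CPM, and Il21 fell 1.52-fold, from 221 ± 11.96 to 146 ± 6.66 CPM. Among the Th9 inducers and products, 10 rose and 9 fell of 34 tested, and 11 and 9 when adjusted over the list alone (camera adjusted p = 0.769), and the list's median of 0.09 and mean of 0.10 had the opposite sign to its test. Among Il9 repressors, 2 rose and 3 fell of 11 tested, and 2 and 4 when adjusted over the list alone (camera adjusted p = 0.811). Foxp3, which is a member of this list, rose 2.03-fold and Klf10 rose 1.66-fold, while Socs3 fell 1.5-fold and Runx3 fell 1.31-fold. The Runx3 call was lost without control replicate 3, without sorafenib replicate 2 or 3 and on unfiltered FPKM (adjusted p up to 0.139 over the alternatives).

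**Figure D1:**
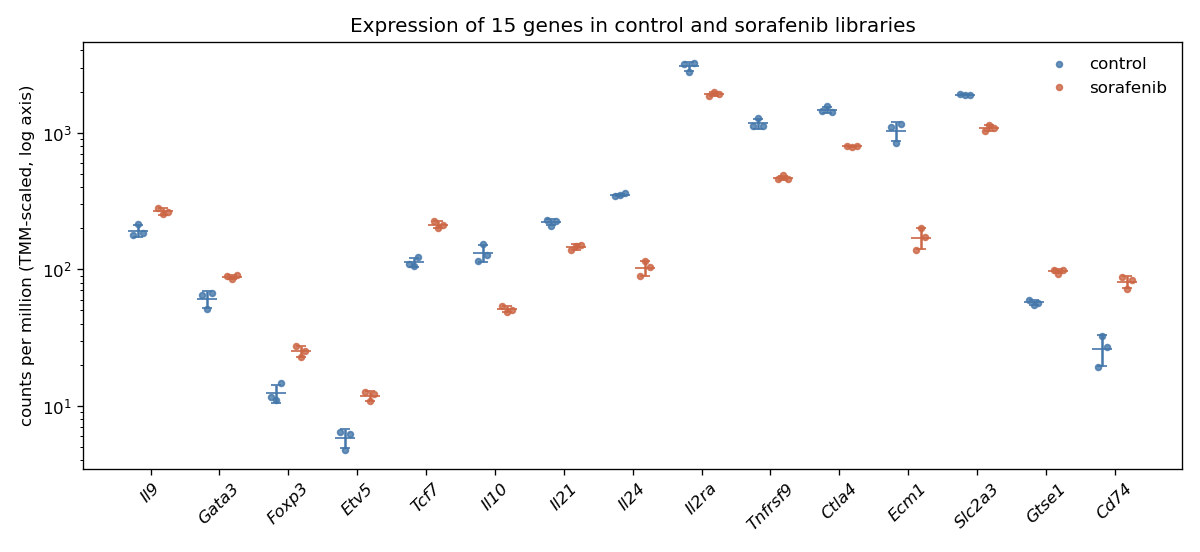
CPM (log axis) of 15 genes in each control and sorafenib library; points are libraries, horizontal marks are group means and bars are SD over 3 libraries. Il9 lies at 192 ± 18.8 CPM in control and 266 ± 15.4 CPM in sorafenib cells, while Il2ra, Tnfrsf9, Ctla4, Il10, Il21, Il24 and Ecm1 lie lower in every sorafenib library than in every control library.

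The 10 largest falls and 10 largest rises are given here for genes whose log2 CPM averaged at least 3 over the 6 libraries; genes below that, Gzma among them, could change more. Ecm1, a secreted matrix glycoprotein, fell 6.03-fold, from 1029 ± 166 to 171 ± 30.6 CPM (log2 fold change -2.59 ± 0.15 SE, adjusted p = 5.66e-06). Enpp2, the enzyme autotaxin, fell 5.22-fold, from 99.8 ± 1.88 to 19.1 ± 0.529 CPM (adjusted p = 7.99e-08). Il12rb2, a chain of the interleukin 12 receptor, fell 5.14-fold, from 76.5 ± 12.2 to 14.9 ± 0.926 CPM, and the granzyme gene Gzmb fell 4.16-fold, from 17.3 ± 1.92 to 4.16 ± 0.81 CPM. Gipr, a hormone receptor gene, fell 3.9-fold, from 292 ± 53.2 to 74.7 ± 9.47 CPM. Adamtsl4, Tgm1, Akr1c18, Pamr1 and Lamc3 fell by 4.44- to 4.94-fold. The largest rises were in Serpina3g (3.93-fold, adjusted p = 2.57e-05), the MHC class II chain H2-Eb1 (3.92-fold, adjusted p = 4.54e-05), Tmem176a (3.2-fold), the class II invariant chain Cd74 (3.1-fold), Zfp365 (2.93-fold) and the integrin Itgae (2.91-fold). Tmem176b, Aqp9, Sorl1 and Clec2i rose by 2.52- to 2.82-fold. Tmem176a and Tmem176b are neighbouring genes, and Serpina3g and Clec2i have close relatives, so reads shared between such genes leave their separate values uncertain.

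Genes of hypoxia and HIF signalling were lower as a group. Of 32 tested, 0 rose and 19 fell, and 20 fell when adjusted over the list alone (camera adjusted p = 5.78e-10, and adjusted p = 0.244 with an estimated correlation). The glucose transporter gene Slc2a3 fell 1.75-fold, from 1903 ± 17.2 to 1089 ± 53.8 CPM, Bnip3l fell 1.6-fold, Adm fell 1.64-fold and Egln3 fell 1.58-fold. In glycolysis genes, 1 rose and 5 fell of 23 tested, and 1 and 10 when adjusted over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.343 with an estimated correlation), with Aldoc 1.38-fold and Hk1 1.27-fold lower and Ldhb 1.72-fold higher. The Hk1 call was lost without control replicate 3, without sorafenib replicate 2 or 3 and on unfiltered FPKM (adjusted p up to 0.0985 over the alternatives). Cholesterol synthesis and uptake genes fell in 15 of 25 and rose in 0, with 17 falling when adjusted over the list alone (camera adjusted p = 3.61e-07, and adjusted p = 0.343 with an estimated correlation). Their enzymes Fdps, Fdft1, Sqle and Lss fell by 1.45- to 1.55-fold, and the calls of Sqle (adjusted p = 0.0529) and Lss (adjusted p = 0.0839) were lost on unfiltered FPKM. In fatty acid synthesis genes, 0 rose and 3 fell of 15 tested, and 1 and 7 when adjusted over the list alone (camera adjusted p = 0.00723, and adjusted p = 0.446 with an estimated correlation), with Elovl6 falling 1.95-fold, Scd1 1.86-fold and Acly 1.33-fold, the calls of the last 2 being lost on unfiltered FPKM (adjusted p = 0.0585 and 0.0765). By edgeR 0 nuclear oxidative phosphorylation genes passed in the main fit, while 3 of 71 had an unadjusted p under 0.05, 1 passed by DESeq2 and 0 by limma-voom; without control replicate 2, 20 were called higher and 1 lower, and every other alternative called 0 to 3. By edgeR 0 ribosomal protein genes passed in the main fit, while 0 of 75 had an unadjusted p under 0.05, 0 passed by DESeq2 and 0 by limma-voom; without control replicate 2, 30 were called higher and 0 lower, with the gene length trend removed 4 higher, and in every other alternative 0. Of 13 mitochondrially encoded genes, 2 fell, ATP6 by 1.45-fold and ND4 by 1.34-fold (camera adjusted p = 0.0779). The ND4 call was lost without control replicate 3, without any 1 of the sorafenib replicates and on unfiltered FPKM (adjusted p up to 0.144 over the alternatives).

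STAT5 and cytokine signalling genes fell in 15 of 28 and rose in 0, with 19 falling and 1 rising when adjusted over the list alone (camera adjusted p = 3.30e-09, and adjusted p = 0.0926 with an estimated correlation). Beside Gzmb, the transcription factor gene Nfil3 fell 1.64-fold, from 405 ± 11.04 to 246 ± 2.93 CPM, Socs3 fell 1.5-fold, from 349 ± 11.3 to 233 ± 8.04 CPM, and the kinase gene Pim3 fell 1.49-fold. Il2ra, the interleukin 2 receptor α chain, fell 1.6-fold, from 3066 ± 237 to 1919 ± 71.1 CPM (adjusted p = 0.00127). In Treg genes, 4 rose and 9 fell of 20 tested, and 6 and 9 when adjusted over the list alone (camera adjusted p = 0.0098, and adjusted p = 0.244 with an estimated correlation). Tnfrsf9 fell 2.5-fold, from 1171 ± 98.6 to 469 ± 16.6 CPM, and Gpr83 fell 2.75-fold, while Foxp3 and Itgae, which belong to the same list, rose. The inhibitory receptor Ctla4 fell 1.84-fold, from 1470.2 ± 75.8 to 797 ± 7.48 CPM. In Th2 genes, 3 rose and 5 fell of 15 tested, and 3 and 6 when adjusted over the list alone (camera adjusted p = 0.0442, and adjusted p = 0.246 with an estimated correlation). Maf fell 1.86-fold and Ccr4 1.37-fold. Ccr3 fell 5.21-fold at a low level, from 1.53 ± 0.219 to 0.291 ± 0.14 CPM. Il4 had 7.23 ± 1.09 CPM in control and 5.68 ± 0.806 CPM in sorafenib cells (adjusted p = 0.169). Il13 had 12.2 ± 1.69 CPM in control and 10.4 ± 0.864 CPM in sorafenib cells (adjusted p = 0.275). The Th2 call was lost without control replicate 3 (adjusted p = 0.0734) and without sorafenib replicate 2 (adjusted p = 0.118). In Tfh genes, 5 rose and 3 fell of 15 tested, and 5 and 3 when adjusted over the list alone (camera adjusted p = 0.0144, and adjusted p = 0.246 with an estimated correlation), with Slamf6 rising 3.61-fold, Pou2af1 2.5-fold and Angptl2 1.83-fold, and this call was lost without control replicate 2 (adjusted p = 0.0921).

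Genes of other T cell lineages were also measured. Tbx21, the Th1 factor, fell 2.02-fold, from 2.54 ± 0.515 to 1.26 ± 0.439 CPM (adjusted p = 0.0381), a call lost without control replicate 1 or 3 and without sorafenib replicate 1 or 3, with total counts only and on unfiltered FPKM (adjusted p up to 0.14 over the alternatives). Ifng had 1.8 ± 0.313 CPM in control and 1.2 ± 0.585 CPM in sorafenib cells (adjusted p = 0.312). Il17a fell 2.29-fold, from 5.57 ± 0.209 to 2.43 ± 0.411 CPM (adjusted p = 0.000952). In cytotoxic effector genes, 3 rose and 6 fell of 15 tested, and 4 and 6 when adjusted over the list alone (camera adjusted p = 0.00858, and adjusted p = 0.343 with an estimated correlation), with a median log2 fold change of 0.03, a mean of -0.49 and a test directed downward. Gzma fell 11.8-fold, from 16.5 ± 2.98 to 1.4 ± 0.397 CPM, and Fasl fell 7.24-fold, while Ccl5 rose 3.55-fold. The cytotoxic call was lost without control replicate 2 (adjusted p = 0.0921), and without genes held by other lists the direction turned upward (adjusted p = 0.736). In CD8 T cell markers, 1 rose and 4 fell of 9 tested, and 1 and 4 when adjusted over the list alone (camera adjusted p = 0.0442, and adjusted p = 0.433 with an estimated correlation), with a median of 0.16 and a mean of -0.52. That list shares Gzmb and Prf1 with the cytotoxic genes, Cd8b1 rose 1.48-fold, a call lost without sorafenib replicate 1 (adjusted p up to 0.0779 over the alternatives), and the list's call was lost without control replicate 2 (adjusted p = 0.0942) and without control replicate 3 (adjusted p = 0.0683). In CD4 T cell markers, 1 rose and 7 fell of 16 tested, and 1 and 9 when adjusted over the list alone (camera adjusted p = 0.00898, and adjusted p = 0.246 with an estimated correlation), with Cd2 falling 1.5-fold, Cd28 1.46-fold and Cd3g 1.31-fold.

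Genes of the G2 and M phases were higher with sorafenib. Of 44 tested, 22 rose and 0 fell, and 30 rose when adjusted over the list alone (camera adjusted p = 9.32e-10, and adjusted p = 0.246 with an estimated correlation). Gtse1 rose 1.7-fold, from 57.2 ± 2.62 to 97 ± 3.67 CPM, Psrc1 rose 1.52-fold, Cdca8 1.39-fold and Ube2c 1.35-fold. In S phase genes, 7 rose and 2 fell of 44 tested, and 10 and 2 when adjusted over the list alone (camera adjusted p = 0.00815, and adjusted p = 0.206 with an estimated correlation), with Tk1 rising 1.72-fold and Ccne2 falling 1.79-fold. In p53 target genes, 14 rose and 0 fell of 27 tested, and 15 and 0 when adjusted over the list alone (camera adjusted p = 1.82e-07, and adjusted p = 0.184 with an estimated correlation). Sesn2 rose 1.64-fold, from 68.4 ± 2.26 to 112 ± 9.82 CPM, and the BH3-only gene Pmaip1 rose 1.6-fold. In integrated stress response genes, 23 rose and 3 fell of 41 tested, and 24 and 3 when adjusted over the list alone (camera adjusted p = 2.39e-08, and adjusted p = 0.343 with an estimated correlation). The amino acid transporter Slc7a3 rose 2.27-fold, Aldh1l2 rose 2.05-fold and Cth, an enzyme of cysteine synthesis, rose 2.36-fold. Sesn2 is also a member of this list.

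Interferon response genes moved both ways, mostly up: 20 rose and 5 fell of 44 tested, and 23 and 6 when adjusted over the list alone (camera adjusted p = 3.40e-06, and adjusted p = 0.184 with an estimated correlation). Oasl2 rose from 0.147 ± 0.109 to 2.54 ± 0.746 CPM and Gbp6 rose 2.59-fold, while Ly6a fell 1.73-fold. In MHC class I genes, 7 rose and 1 fell of 16 tested, and 8 and 1 when adjusted over the list alone (camera adjusted p = 0.000421, and adjusted p = 0.343 with an estimated correlation). Nlrc5, an activator of class I transcription, rose 1.83-fold, H2-T22 rose 1.63-fold, Tap1 1.32-fold and Psmb9 1.51-fold. In NF-kappaB response genes, 11 rose and 2 fell of 25 tested, and 11 and 3 when adjusted over the list alone (camera adjusted p = 0.00858, and adjusted p = 0.343 with an estimated correlation), with Nfkb2 rising 1.58-fold and Nfkbie 1.67-fold, and Traf1 falling 1.55-fold. Members of the Oasl, Gbp, Ly6 and H2 families have close relatives and may share reads with them, which leaves single values uncertain.

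Several lists of markers of other cell types moved with these groups. Mast cell and basophil markers did not, with 0 of 5 tested called (camera adjusted p = 0.811). The tested members include Il4 and Il13, which also stand among the Th2 genes, so the list is not particular to those cells. Of 4 tested erythroid and platelet markers 0 were called, too few for a list test. In B cell markers, 11 rose and 2 fell of 14 tested, and 12 and 2 when adjusted over the list alone (camera adjusted p = 3.25e-08, and adjusted p = 0.252 with an estimated correlation). H2-Eb1 rose from 10.4 ± 2.93 to 40.6 ± 3.83 CPM, Cd74 rose from 26.2 ± 6.65 to 81 ± 8.43 CPM and Spib rose 6.6-fold, while Ebf1 fell 3.43-fold, from 19.6 ± 0.946 to 5.72 ± 0.897 CPM. In macrophage, monocyte and dendritic cell markers, 6 rose and 2 fell of 17 tested, and 6 and 2 when adjusted over the list alone (camera adjusted p = 0.000496, and adjusted p = 0.246 with an estimated correlation). That list shares 4 class II genes with the B cell markers, of which H2-Aa rose 3.22-fold and H2-Ab1 fell 1.5-fold, from 244 ± 32.2 to 163 ± 4.7 CPM. Without genes that other lists hold, its adjusted p was 0.282. In stromal and endothelial markers, 0 rose and 4 fell of 6 tested, and 0 and 5 when adjusted over the list alone (camera adjusted p = 5.72e-05, and adjusted p = 0.184 with an estimated correlation). Pecam1 of this list fell 1.88-fold from a mean of 50.8 CPM in control. The epithelial genes Epcam and Krt18, which this fixed list also holds, fell 4.99-fold and 2.4-fold. Ly6g had 120 to 125 counts in each control library and 0 to 2 in each sorafenib library, and Cxcr2 fell 2.61-fold, while the neutrophil list had too few tested members for a list test. With camera's preset correlation 21 of 46 lists passed, and with an estimated correlation 0 did, with 8 at an unadjusted p under 0.05 and 25 by fry. By rank-based camera the CD8, cytotoxic, NF-kappaB, Tfh, Th2 and Treg lists did not pass (adjusted p from 0.174 to 0.665). Without genes shared between lists, the NF-kappaB (adjusted p = 0.0964), Th2 (0.0811) and Treg (0.277) lists did not pass either.

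**Figure D2:**
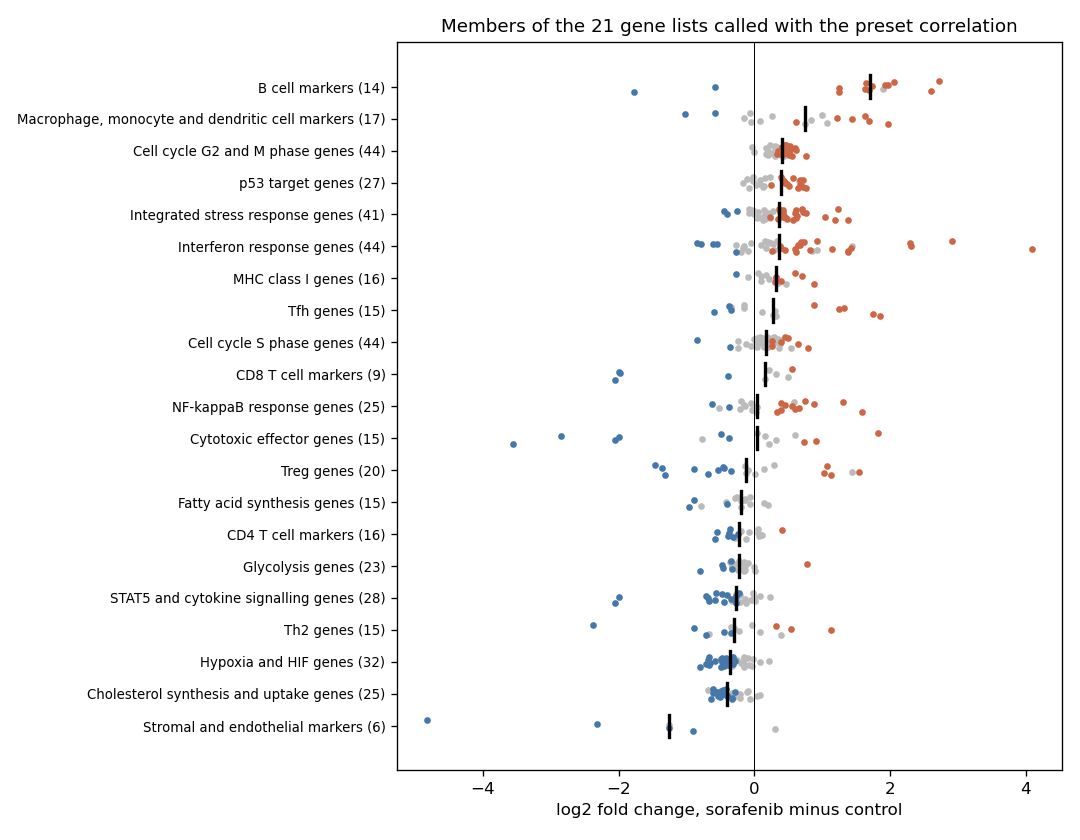
Log2 fold change (sorafenib minus control) of every tested member of the 21 lists called with the preset correlation; orange and blue points passed the gene test upward and downward, grey points did not, and black bars are list medians. Numbers in brackets are tested members. The hypoxia median was -0.36 and the G2 and M phase median 0.41, while none of the 21 calls held with an estimated correlation.

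One control library stood apart. The first principal component, with 51.4% of the variance, separated the groups, and the second, with 22.4%, separated control replicate 2 from the rest. Control replicate 2 had the lowest TMM factor, 0.922 against 0.993 and 1.01 in the other controls, and 17.0% of its counts in ribosomal protein genes against 13.8% and 13.4%. The median difference in log2 CPM from the mean of the other controls was 0.24 over the 3314 shortest genes and -0.20 over the 3314 longest. Every pair of libraries within a group differed by more than sampling noise, with chi-square per degree of freedom of at least 6.15. Xist had 1008 ± 525 CPM in control and 793 ± 50.7 CPM in sorafenib cells (adjusted p = 0.58), and was called, as lower, without control replicate 2 (adjusted p = 0.0257). It had 15656 counts in control replicate 2, against 55918 and 40207 in control replicates 1 and 3, and the cause was not tested.

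**Figure D3:**
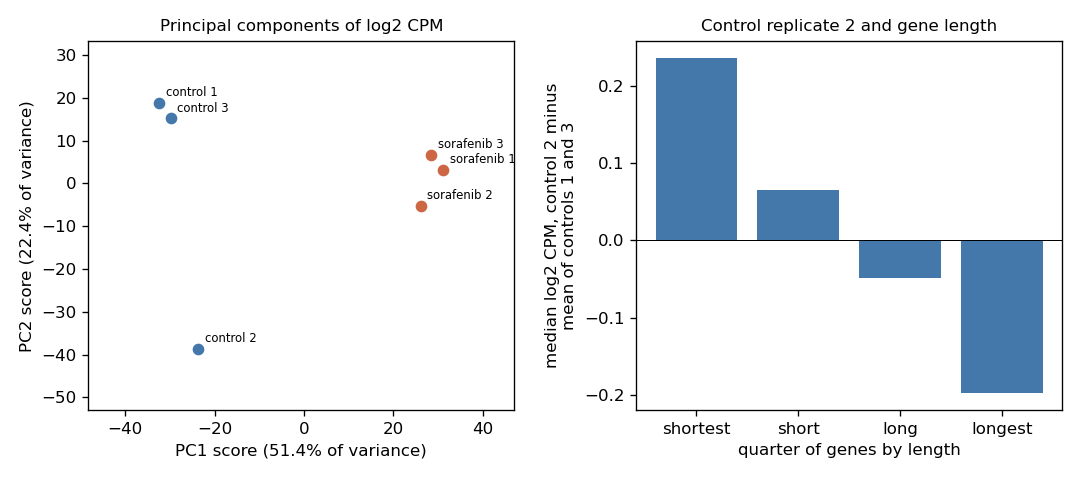
Left, scores of the 6 libraries on the first principal components of log2 CPM, with control replicate 2 at -38.6 on the second axis. Right, the median difference in log2 CPM between control replicate 2 and the mean of controls 1 and 3 in 4 bins of genes by length, from 0.24 in the shortest to -0.20 in the longest.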

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

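The genes called numbered 1606 to 2639 for the other scalings, filters, tools and FPKM values, and the named genes that had passed the test kept their direction in every alternative that gave them a value. Leaving out 1 library gave 1243 to 4325 genes, the most without control replicate 2 and the fewest without sorafenib replicate 3. These fits have fewer samples, and that alone cannot explain a higher count. Control replicate 2 differed from controls 1 and 3 with chi-square per degree of freedom of 62.6 and 50.9, against 15.4 between those. Leaving it out thus lowered the spread among controls, which goes with the higher count. No other cause was tested. Stricter thresholds, by their construction, called fewer: 1227 at an adjusted p under 0.01, 560 at an adjusted p under 0.05 with at least a 2-fold change, and 1059 when tested against a 1.2-fold change. Total counts only called 1496 higher and 826 lower, 64.4% higher against 47.4%, and FPKM values 65.3%. Leaving out 1 library moved the log2 fold change of Xist, not called in the main fit, across 0, from -0.69 without control replicate 2, where it was called (adjusted p = 0.0257), to 0.054 without control replicate 1. Without control replicate 2 Irf4, Batf and Braf were also called. Without a filter, log2(FPKM + 1) ended the calls of 20 named genes.

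With an estimated correlation 0 lists passed instead of 21. That setting widens the variance of lists whose genes vary together, and it also rests on the 4 residual degrees of freedom. Which of these ended each call was not tested. Leaving out 1 library gave 20 to 23 lists, and the rank-based test and lists without shared genes 16 each. With the replicate block 2139 genes and 21 lists were called, and the Th2 list was not (adjusted p = 0.0629); of the named genes 6 were no longer called, ND4 among them (adjusted p = 0.0572). The labels do not say whether the numbers pair the samples. The correlations of same-numbered deviations were -0.063, 0.15 and 0.10. Controls 2 and 3 correlated best with their own number and control 1 did not. With 3 libraries per group this cannot tell whether the samples are paired. Chosen after seeing the data, removal of the gene length trend called 3197 genes and removal of the GC trend 2363. Genes near the floor of 0.0787 to 0.0811 CPM are limited by depth.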

Other observations

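The tests of gene length and abundant genes in control replicate 2, and those of myeloid markers and of the T cell share, were chosen after the result was seen, and so were the corrections for gene length and GC content. Several fixed groups were not called by camera, with members that passed the gene test in opposite directions. Of the groups in this part, fry, which does not compare a list with other genes, called sorafenib target kinases (adjusted p = 0.0475), apoptosis regulators (adjusted p = 0.0163), immediate early genes (adjusted p = 0.013) and NK and innate lymphoid markers (adjusted p = 0.0164). In ERK pathway response genes, 11 rose and 7 fell of 35, with Egr3 rising 2.24-fold, from 8.97 ± 0.966 to 20.1 ± 3.38 CPM, and Lif falling 1.6-fold, from 643 ± 80.1 to 403 ± 18.98 CPM, a call lost on unfiltered FPKM (adjusted p = 0.0571). Among sorafenib target kinases, 2 rose and 4 fell of 11, with Mapk14 rising 1.47-fold and Flt3 2.33-fold, Fgfr1 falling 1.71-fold and Braf at 55.1 ± 9.56 CPM in control and 46.5 ± 1.95 CPM in sorafenib cells, not called except without control replicate 2 (adjusted p = 0.000258) and with the gene length trend removed (adjusted p = 0.033). In TGF-beta response genes, 9 rose and 6 fell of 29, with Timp1 falling 2.84-fold, against a rise in Itgae. In T cell activation genes, 10 rose and 6 fell of 28, with Nr4a3 rising 2.14-fold, and in checkpoint receptor genes, 4 rose and 3 fell of 16, with Tox rising 3.36-fold from a low level.

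In naive and memory T cell genes, 7 rose and 4 fell of 22. Tcf7 rose 1.89-fold, from 113 ± 8.37 to 213 ± 13.8 CPM, while Il7r fell 1.55-fold. In chemokine genes, 4 rose and 5 fell of 19, with Cxcr4 falling 1.62-fold. In Th1 genes, 6 rose and 4 fell of 18, and in Th17 genes, 3 rose and 5 fell of 14, with Il17f falling 2.3-fold. In apoptosis regulators, 8 rose and 2 fell of 27. In autophagy and lysosome genes, 5 rose and 7 fell of 45, with Gla falling 1.83-fold and Gpnmb rising 2.99-fold. In ribosome biogenesis and Myc target genes, 0 rose and 3 fell of 38, with Mycn falling 6.1-fold and Eif5a 1.37-fold, the Eif5a call being lost without sorafenib replicate 1 or 3 (adjusted p up to 0.0602 over the alternatives).

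Among ER chaperone genes 1 rose and 5 fell of 27, among heat shock genes 1 rose and 2 fell of 18, among NRF2 and ferroptosis genes 4 rose and 1 fell of 33, among LXR and cholesterol efflux genes 2 rose and 1 fell of 10, among NK and innate lymphoid markers 1 rose and 3 fell of 8, among immediate early genes 3 rose and 6 fell of 19. Several of these calls hung on single libraries. Without sorafenib replicate 3 every LXR call of the main fit was lost (adjusted p from 0.0621 to 0.18). Some NRF2 calls were lost without sorafenib replicate 1 or 3 (up to 0.175). The ER chaperone rise was lost without control replicate 1 or 3 and sorafenib replicate 1 or 3 (up to 0.13). The heat shock rise was lost without any 1 library except control replicate 2 (up to 0.123).

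The real grouping called 2378 genes, and the highest of the 9 other splits of the 6 samples into 3 and 3 called 0 by edgeR, with 61 to 649 genes at an unadjusted p under 0.05. No other tool was run on these splits. For lists the real grouping called 21 and the highest other split 17, the lowest 9. Each other split put unequal numbers of control and sorafenib libraries on each side. Part of the difference between the groups thus stayed in the contrast, and the rest widened the spread within each side. These splits therefore cannot tell whether the list test with its preset correlation calls too many lists. For genes and for lists alike, 1 of the 10 splits gave a result as large, the real one, and 10 splits are too few for a share under 0.05.

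B cell and MHC class II markers were higher with sorafenib at the preset correlation, and the B cell list did not pass with an estimated one (adjusted p = 0.252). A candidate explanation is a larger share of B cells in those libraries. Of 14 other B-cell genes that were listed before the test was run, though the values of 1 of them, Cd40, had been seen by then, 7 rose and 1 fell, with a median log2 fold change of 0.94 (SD 0.99 over genes), which goes with it, though Ebf1 and H2-Ab1, each with a control level that would hide a small share, fell. Of the 21 fixed B cell markers, 17 were among the measured genes and 14 were tested, and 5 also stand in another list. The immunoglobulin genes Ighm, Ighd, Igkc and Iglc2 of that list, and Ms4a1, Cr2 and Vpreb3, gave no tested value. Myeloid markers without the class II genes had a median of 0.62 (SD 0.69), so macrophages or dendritic cells stay open too, but 3 of 13 rose and 1 fell, and Apoe, named after its values were seen, had 16.8 CPM in control and 17.8 CPM in sorafenib libraries. A lower share of T cells would raise markers of every other type, and the 6 tested genes of the stromal and endothelial list had a median of -1.26 (SD 1.74). Without the epithelial genes Epcam and Krt18 the other 4 had a median of -1.08 (SD 2.20), with 2 lower and 2 not called, against 1.71 for the B cell markers. In control libraries Lum, Kdr and Col1a1 of these averaged only 0.818, 0.988 and 0.74 CPM. Such few genes of mostly low level cannot decide on a lower share of T cells. CD4 T cell markers were lower (camera adjusted p = 0.00898, and adjusted p = 0.246 with an estimated correlation). An effect of sorafenib on the T cells' own expression stays open and was not tested.

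Control replicate 2 differed from controls 1 and 3 with a spread over genes 2.10 times that expected from the difference between those 2. Removing the trend on gene length lowered this to 1.57 (bootstrap SD over genes 0.028), so length goes with part of the difference and not the whole of it. Leaving out the 14 genes that were among the 10 most abundant of any library left it at 2.0976, against 2.0986 before. No biological explanation was tested, since the labels give none within a group.

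Hypoxia and HIF genes had a median log2 fold change of -0.36. It was -0.34 with the gene length trend removed, -0.3572 with the GC trend removed and -0.29 without control replicate 2, and the list passed its preset-correlation test each time (adjusted p = 2.52e-12, 8.59e-11 and 7.19e-10), which argues against each as the whole cause. Its adjusted p was 0.244 with an estimated correlation, a setting that rests on 4 residual degrees of freedom. The other splits of the samples mixed the groups and cannot decide this. Shared variation among these genes stays open beside an effect of sorafenib.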
